A study of Homo sapiens with 64 samples.

How the data were processed

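RNA was isolated from scraped tissue sections of control skin and BCC with a RecoverAll kit, which is made for fixed, paraffin-embedded tissue, and converted to small RNA libraries with the QIAseq miRNA kit, per the labels' protocols and the series' design text. The tumours had been chosen to make up most of each specimen, per the series' design text. The authors deposited 1 table of estimated counts, with 2652 human mature miRNAs and 64 libraries, and 51.6% of its values above 0 were whole numbers within 0.001. How values that are not whole came about, for instance by sharing a read among several miRNAs, is not given in the sources used here. STAR 2.7.9a, featureCounts 1.6.3 and DESeq2 1.36.0 are named per the submitters' processing notes, with the genome build GRCm39. That build is a mouse assembly, while every miRNA in the table has a human name, and how the build entered the counting is not given in the sources used here. Handling of the unique molecular identifiers that this kit adds is likewise not given in the sources used here, so depth is stated in counts as deposited.

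Every column matched 1 sample by its name, and each sample's group came from its labels. The expected counts were rounded to whole numbers, which changed a library total by at most 47.6 reads. The tests had been laid out for raw counts, and the same count tests were used on the rounded expected counts. Totals ran from 0.928 to 6.67 M reads, and 2279 miRNAs had at least 1 read. A filter (edgeR filterByExpr, minimum count 10) left 582 miRNAs, which held 99.9% of the reads in the library with the lowest share. The median biological coefficient of variation was 0.456.

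Groups were compared with edgeR 4.0.16 in R 4.3.3: TMM scaling, a robust quasi-likelihood fit of 5 groups over all 64 libraries, a two-sided F-test and Benjamini-Hochberg adjustment, with a call at an adjusted p under 0.05. The SE of a log2 fold change was its size divided by the square root of F. BCC against control skin took the unweighted mean of the 4 subtypes, and infiltrative and micronodular against nodular and superficial BCC took the means of each pair. In all, 12 comparisons were made. Log2 CPM for the principal components and PERMANOVA (vegan 2.7.1, 10000 permutations with the observed order) used a prior count of 2. The tests, the miRNA lists, the rule for named miRNAs and the alternatives, apart from those given as added, were chosen before the data were examined.

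The 20 miRNA lists were epithelial, keratinocyte differentiation, smooth muscle, striated muscle, fibroblast and mesenchymal, endothelial, erythroid, leukocyte and melanocyte miRNAs, the miR-17-92 cluster with its paralogs, the let-7, miR-29, miR-34 and miR-181 families, the miR-183 cluster, the 14q32 cluster, miRNAs that repress Hedgehog pathway genes, miRNAs linked to invasion in other carcinomas, and miRNAs that earlier BCC reports gave as higher or as lower. They were tested with limma 3.58.1 (camera, preset correlation 0.01), with an estimated correlation and the fry test as alternatives. The lists for earlier reports of higher miRNAs and the miR-183 cluster had 1 member in common, as did those for earlier reports of lower miRNAs and smooth muscle, and for keratinocyte differentiation and the miR-34 family. The miRNAs named were the 5 most abundant, the 10 highest and 10 lowest fold changes of the comparisons of BCC with control skin and of infiltrative and micronodular with nodular and superficial BCC, and the 3 highest and 3 lowest of each other comparison, among those called and with a group mean of at least 10 CPM. Up to 4 members of each list, those with the smallest p, could be named as well.

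The alternatives tried were DESeq2 1.42.0, limma-voom with quality weights, RLE factors, library totals only, no filter, a stricter filter of 10 CPM in 9 libraries, depth as a covariate, the compared groups alone, pooled groups weighted by their libraries, the 6 shallowest libraries left out, and each library left out in turn. Added after the data were seen were thinning every library to the smallest total of 927831 reads, removing each library's trend with GC content (known for 574 of the 582 miRNAs), and leaving out the 5 libraries that stood apart. Figures were drawn with matplotlib 3.10.9. The table gives no coordinates, so positions of miRNA genes were taken by name from GENCODE release 29 on GRCh38.

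The tests were tested on simulated data with known changes. For BCC against control skin, edgeR recovered 40.0% of miRNAs changed 1.5-fold, 78.7% of those changed 2-fold and 96.6% of those changed 4-fold, on 553 miRNAs, and 5 of 133 calls were false. For micronodular against nodular BCC it recovered 16.7%, 57.1% and 95.4% on 569 miRNAs, and 3 of 112 calls were false. For infiltrative and micronodular against nodular and superficial BCC it recovered 59.4%, 89.2% and 100% on 565 miRNAs, and 10 of 170 calls were false. Each miRNA was drawn separately from the spread that edgeR had fitted, with the same mean in all groups before the changes. No correlation among miRNAs, outlying libraries or GC trend was built in. The false shares therefore need not hold for the real libraries, where a random split gave up to 70 calls for micronodular against nodular BCC.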

Results

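MicroRNAs (miRNAs), short RNAs that repress messenger RNAs with matching sites, were sequenced from 64 human skin specimens. Of these, 9 were control skin and 55 were basal cell carcinoma (BCC), a keratinocyte cancer driven by Hedgehog signalling. The tumours belonged to 4 histologic subtypes, superficial (n = 13), nodular (n = 10), micronodular (n = 10) and infiltrative (n = 22), and the series asks which miRNAs mark them. Median depth was 6.0 M miRNA reads per library in control skin, 2.75 in superficial, 3.69 in nodular, 3.58 in micronodular and 2.23 in infiltrative BCC, over a range of 0.928 to 6.67 M reads. The control libraries were the deepest in the median, while the ranges overlapped, with control skin at 4.44 to 6.67 and nodular BCC at 2.66 to 6.34 M reads. The 5 miRNAs with the highest mean level over all 64 libraries took 26.6% ± 2.26 (SD, n = 9) of the reads in control skin. In infiltrative BCC the same 5 took 40.8% ± 5.46 (SD, n = 22). They were a fixed set, mostly weighted by tumour libraries, and need not be the most abundant miRNAs of control skin. No pair of libraries within a group held identical values or agreed within sampling noise, the lowest chi-square per degree of freedom being 91.0. The labels do not state that the specimens came from separate patients, so p-values measure only the spread between these samples, which may be technical. Names are given without the hsa- prefix, levels are CPM (read counts scaled to a common library size) after TMM scaling, and each log2 fold change carries its standard error (SE).

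The 5 groups differed in their whole profiles. Group accounted for 40.2% of the variance over the 582 miRNAs tested (permutational multivariate analysis of variance, permutation p = 1e-04, the smallest that 10000 permutations can give), and subtype for 26.7% among the 55 tumours (permutation p = 1e-04). On the first principal component, control skin lay between -27.3 and -19.7 and infiltrative BCC between 3.43 and 18, with superficial BCC between them at -19.7 to 1.86. Superficial library 7, at -19.7, lay beside the control libraries, and micronodular libraries 3 and 4 were lowest on the third component at -21.8 and -21.7. Infiltrative 7 was at -15.9 on that component and micronodular 1 and 2 at -12.1 and -10.4. Superficial 7 and micronodular 1 to 4 stood apart from the other libraries in their rise of level with GC content, 0.303 log2 per 10 points in superficial 7 and 0.309, 0.297, 0.638 and 0.553 in micronodular 1 to 4, against -0.163 to 0.0017 in the other micronodular libraries and at most 0.161 in any other library.

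**Figure D1:**
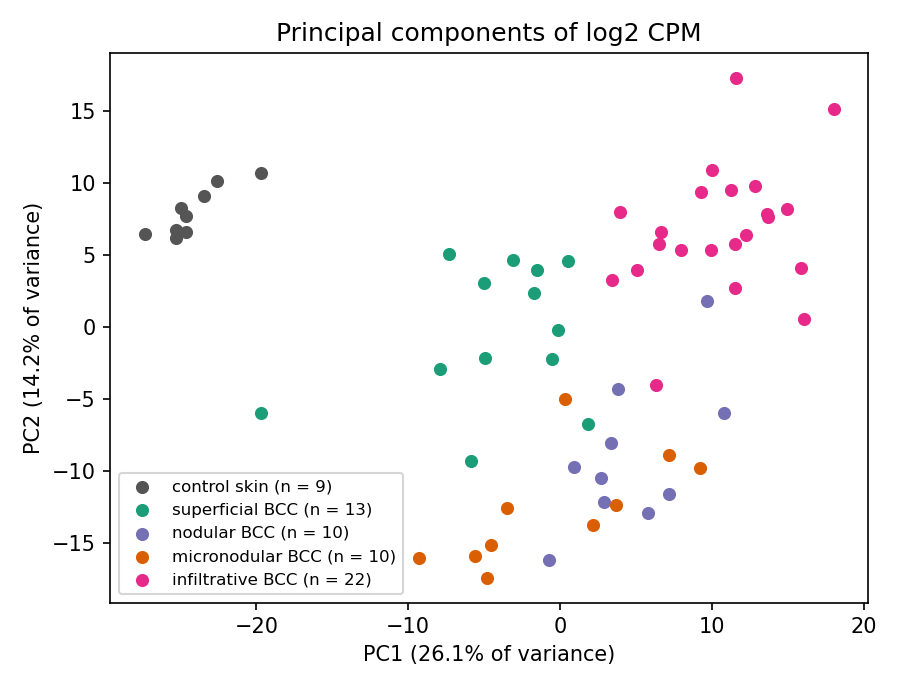
First principal component (26.1% of variance) against the second (14.2%) for the 64 libraries, 1 point per library, coloured by group. The control libraries sit at -27.3 to -19.7 on the first component and the infiltrative libraries at 3.43 to 18.

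Comparing all BCC with control skin, the 4 subtypes weighted equally, miR-1269a was the most raised miRNA. Its mean was 65.3 CPM in BCC (n = 55) and 0.549 CPM in control skin (n = 9), a log2 fold change of 6.53 ± 0.96 (edgeR, adjusted p = 3.54e-08), and 53 of 55 tumours exceeded the control median. Neighbouring miRNAs of an X-linked cluster rose in every tumour relative to that median: miR-450a-5p by 4.34 ± 0.45, miR-424-3p by 3.84 ± 0.42 and miR-450b-5p by 3.70 ± 0.42 log2. The largest fall was that of miR-383-5p, from 37.7 to 0.929 CPM (log2 fold change -5.40 ± 0.38; edgeR, adjusted p = 2.50e-19), and each of the 55 tumours lay below every control library. Vessel and muscle miRNAs were among the next largest falls, with miR-145-5p of smooth muscle at -3.01 ± 0.23, miR-126-3p of endothelium at -2.60 ± 0.17, and the striated muscle miRNAs miR-133a-3p and miR-1-3p at -3.60 ± 0.40 and -2.71 ± 0.46. Among the 5 most abundant miRNAs, miR-205-5p, typical of basal keratinocytes, rose 3.01-fold to 94420 CPM and miR-21-5p, raised in many carcinomas, rose 2.82-fold. The keratinocyte differentiation miRNA miR-203a-3p (-0.35 ± 0.22; adjusted p = 0.151) and let-7b-5p (-0.31 ± 0.16; adjusted p = 0.0916) did not pass the test.

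The other named miRNAs that rose were miR-1269b (5.82 ± 1.73), miR-135a-5p (5.01 ± 0.97), the neuronal miR-124-3p (4.80 ± 1.23), miR-105-5p (4.68 ± 1.55), miR-7977 (4.52 ± 0.68) and miR-767-5p (4.17 ± 1.49). Those that fell were miR-10a-3p (-3.18 ± 0.33), the erythroid miR-144-3p (-2.73 ± 0.47), miR-4524a-3p (-2.51 ± 0.31), miR-139-3p (-2.50 ± 0.31) and miR-145-3p (-2.34 ± 0.18). In all, 389 of 582 miRNAs passed an edgeR adjusted p of 0.05, with 228 higher and 161 lower in BCC and 253 changed at least 2-fold. The split was 241 higher and 283 lower with no filter on low counts and 209 and 196 without the 5 libraries that stood apart. With the GC trend removed, 204 of 386 calls were higher. Scaling by library totals alone gave 268 higher and 115 lower, and moved the median log2 fold change of all miRNAs from 0.19 to 0.50. The fall of let-7a-5p (-0.31 ± 0.12; adjusted p = 0.0253) stood at -0.02 under library totals and 0.01 with depth as a covariate, and was not called with libraries thinned (-0.13), with the subtypes weighted by their libraries (-0.39), or without control library 1, 4 or 6 (adjusted p = 0.0539, 0.0741 and 0.0570). The X-linked miR-105-5p and miR-767-5p exceeded the control median in 27 of 55 tumours each. Leaving out superficial 3, nodular 4 or micronodular 7 gave 3.82, 3.31 and 3.99 for miR-105-5p and 3.33, 2.75 (adjusted p = 0.0534) and 3.24 for miR-767-5p. DESeq2 called neither (2.18 and 0.93), and limma-voom did not call miR-767-5p (0.73). With the subtypes weighted by their libraries miR-144-3p was at -1.39 and not called. The value of miR-124-3p was 3.66 without superficial 9, and that of miR-1269b was 6.64 without control 9.

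MIR1269A lies in no annotated gene on chromosome 4 (66276824 to 66276928, GRCh38), and MIR1269B in an intron of ARHGAP44, on the opposite strand (chromosome 17, 12917268 to 12917342). MIR383 lies in an intron of SGCZ (chromosome 8, 14853438 to 14853510), MIR126 in an intron of EGFL7 (chromosome 9, 136670602 to 136670686), and MIR145 in an intron of the non-coding gene CARMN (chromosome 5, 149430646 to 149430733), whose exon holds MIR143 (149428918 to 149429023). Both copies of the miR-105 gene lie in an intron of GABRA3 on chromosome X (152392219 to 152392299 and 152394412 to 152394492). The near-identical sequences of miR-1269a and miR-1269b, of the let-7 and miR-181 families, of miR-17-5p and miR-106a-5p and of the miR-199 pair make the split of reads among them uncertain.

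Smooth muscle, vessel, striated muscle, mesenchymal and erythroid miRNAs were lower as groups in BCC than in control skin with the subtypes weighted equally. All 4 smooth muscle members fell, among them miR-143-3p (-2.22 ± 0.18; camera adjusted p = 1.87e-04, and adjusted p = 0.0882 with an estimated correlation). Both endothelial members fell, miR-126-5p by 2.31 on the log2 scale (camera adjusted p = 0.00495, and adjusted p = 0.0882 with an estimated correlation). They are arms of the same hairpin, MIR126, and the smooth muscle members are arms of MIR143 and MIR145, both within CARMN. In every comparison such members are not separate evidence, while camera's preset correlation of 0.01 treats them as nearly independent. Of 3 striated muscle members 2 fell (camera adjusted p = 0.0398; adjusted p = 0.172 with an estimated correlation), and of 6 fibroblast and mesenchymal members 4 fell, including miR-199a-5p at -1.52 ± 0.18 and miR-199b-5p at -1.55 ± 0.18 (camera adjusted p = 0.0173; adjusted p = 0.302 with an estimated correlation). All 4 erythroid members fell (camera adjusted p = 0.0374; adjusted p = 0.322 with an estimated correlation), though the erythroid median in infiltrative BCC alone was 0.09. The miR-29 family, which represses collagen genes, fell in 4 of 4 members (miR-29c-5p -1.40 ± 0.17; camera adjusted p = 0.0103, and adjusted p = 0.222 with an estimated correlation). Of 27 miRNAs of the imprinted 14q32 cluster 19 fell and 2 rose, miR-377-3p (1.97 ± 0.35) and miR-493-5p (0.95 ± 0.26) being those that rose (camera adjusted p = 1.87e-04; adjusted p = 0.302 with an estimated correlation). With library totals 15 of these fell and 2 rose. Among 8 leukocyte miRNAs 2 rose, miR-155-5p by 1.25 ± 0.25 and miR-142-3p by 1.02 ± 0.34 (camera adjusted p = 0.962). The leukocyte median was 0.26 while camera's direction was down.

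The miR-181 family, the miR-183 cluster and the miR-17-92 group were higher in BCC than in control skin. All 4 members of the miR-181 family rose, miR-181c-5p by 3.35 ± 0.32 and miR-181d-5p by 3.24 ± 0.34 (camera adjusted p = 5.26e-04; adjusted p = 0.0882 with an estimated correlation). The 3 miRNAs of the miR-183 cluster rose, led by miR-96-5p at 3.66 ± 0.49 (camera adjusted p = 0.0110; adjusted p = 0.222 with an estimated correlation). In the proliferation-linked miR-17-92 group and its paralogs 9 of 12 rose, such as miR-20a-5p at 2.41 ± 0.25, and miR-20b-5p (-1.04 ± 0.22) and miR-363-3p (-0.74 ± 0.33) fell (camera adjusted p = 0.00835; adjusted p = 0.297 with an estimated correlation). Without control 3, 4, 6 or 7 miR-363-3p was not called (-0.74 to -0.62; adjusted p = 0.0555 to 0.107). Of 6 epithelial miRNAs 5 rose, including miR-429 at 1.11 ± 0.27, and of 7 melanocyte miRNAs 5 rose, including miR-506-3p at 2.38 ± 0.47, but neither list passed camera (adjusted p = 0.103 each). Of 13 miRNAs that earlier BCC reports gave as higher, 12 rose and miR-125a-5p fell by 1.23 log2 (camera adjusted p = 7.15e-05; adjusted p = 0.0882 with an estimated correlation). This list shares 6 members with the miR-17-92 list and 2 with the miR-181 family. Of 6 given earlier as lower, 5 fell, among them miR-140-3p at -1.62, and 2 of the 6 also belong to the miR-29 family (camera adjusted p = 0.00161; adjusted p = 0.0882 with an estimated correlation).

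Several lists did not pass camera in BCC against control skin, and some of them turned with the scaling. Of 9 let-7 miRNAs 6 fell, let-7e-5p by 0.63 log2, but with library totals 1 fell and 2 rose (camera adjusted p = 0.103). Of 7 keratinocyte differentiation miRNAs 3 fell, miR-574-3p at -2.15 ± 0.21 the most, while 5 fell without superficial 7, and with library totals 1 fell and 2 rose (camera adjusted p = 0.173). In the miR-34 family 1 rose and 2 fell, miR-34a-5p by 0.59 log2, where library totals gave 2 higher and 0 lower (camera adjusted p = 0.610, direction down against a median of 0.15). In that family 1 fell without control 2, 4 or 5, and 2 rose without any 1 of nodular 3, 6, 7 and 10 and micronodular 1, 2, 3 and 5. Of 3 miRNAs that repress Hedgehog pathway genes, miR-125b-5p fell (-1.42 ± 0.23; camera adjusted p = 0.226), and 2 fell without any 1 of superficial 3, 6, 7, 9, 11 and 13, nodular 1 and 2, micronodular 3, and infiltrative 3, 5, 8, 15 and 16. Of 6 miRNAs linked to invasion in other carcinomas 5 rose, miR-31-5p by 2.36 ± 0.55, and miR-10b-5p fell (-0.85 ± 0.18; camera adjusted p = 0.337), but 2 rose without superficial 7, and 3 without any 1 of superficial 6, 9, 11 and 13 and infiltrative 3, 5, 8 and 15. Counts adjusted over the list alone equalled those over all miRNAs for each of the 20 lists except the miR-34 family, with 2 higher and 2 lower, and in the other comparisons they are given where they differed for a list described. The members that went against their list, miR-377-3p, miR-493-5p, miR-20b-5p, miR-363-3p and miR-125a-5p here and miR-98-5p in infiltrative BCC, were picked after their values were seen.

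**Figure D2:**
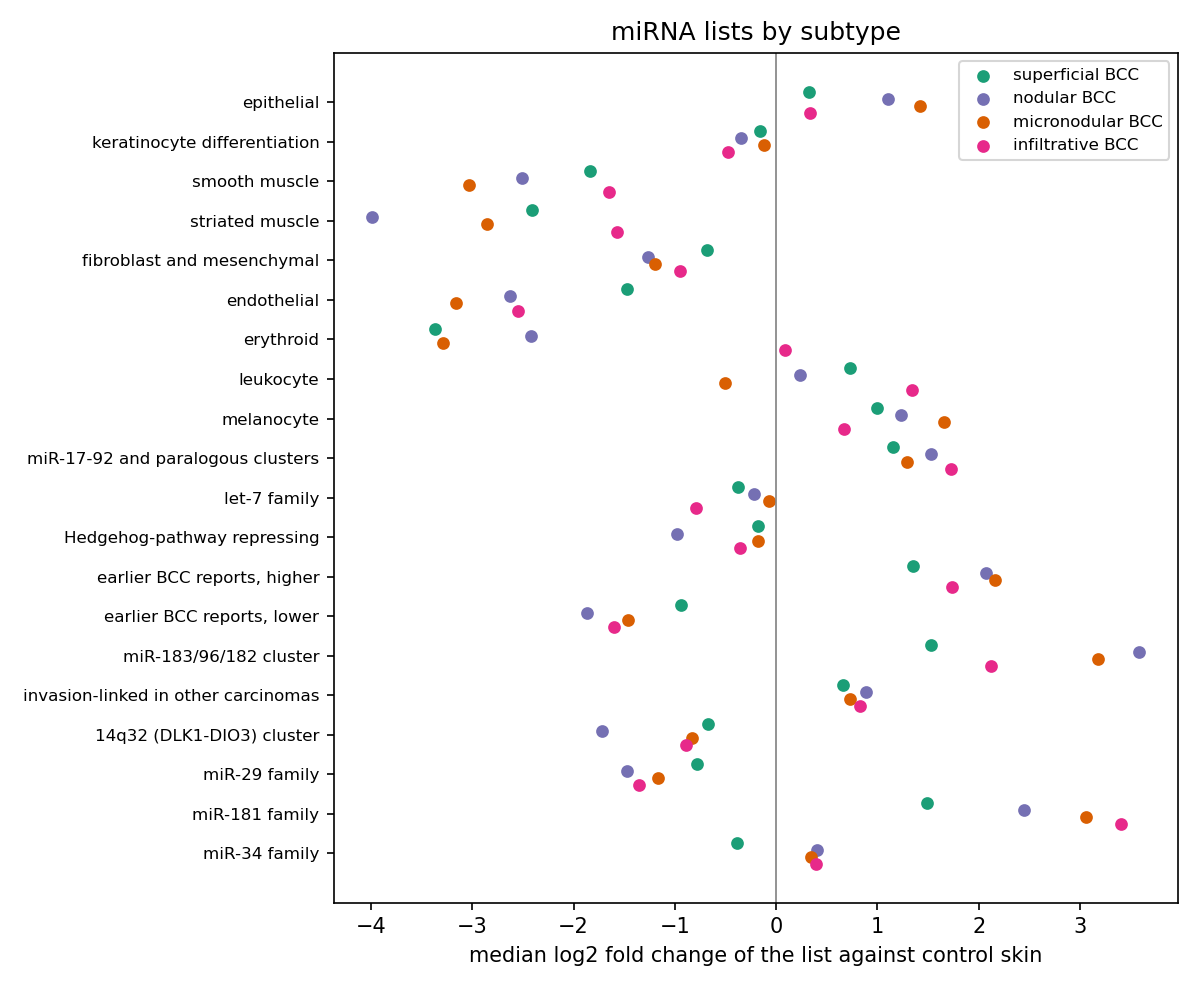
Median log2 fold change against control skin of each of the 20 miRNA lists, 1 point per histologic subtype (superficial n = 13, nodular n = 10, micronodular n = 10, infiltrative n = 22, control n = 9). The endothelial medians run from -3.16 to -1.48 and the miR-181 family medians from 1.49 to 3.41.

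Superficial BCC was set against control skin, which does not by itself separate it from the other subtypes. The largest rises were in miR-1269b (6.39 ± 1.83), miR-124-3p (6.12 ± 1.34) and miR-1269a (4.63 ± 0.94; edgeR, adjusted p = 5.84e-05), and the largest falls in miR-383-5p (-4.67 ± 0.59; adjusted p = 1.26e-08), miR-144-3p (-3.57 ± 0.69) and miR-451a (-3.39 ± 0.75). In the 13 tumours, miR-383-5p and miR-144-3p lay below every control library. Erythroid miRNAs fell in 4 of 4 members (camera adjusted p = 0.00482; adjusted p = 0.241 with an estimated correlation). Smooth muscle miRNAs fell in 4 of 4, miR-145-5p by 2.29 log2 (camera adjusted p = 1.44e-04; adjusted p = 0.188 with an estimated correlation), and miR-181 miRNAs rose in 4 of 4, miR-181d-5p by 2.06 ± 0.35 (camera adjusted p = 0.00779; adjusted p = 0.195 with an estimated correlation). Of 8 leukocyte miRNAs 4 rose, without passing camera (adjusted p = 0.0734). Of these, the lymphocyte miR-150-5p (1.09 ± 0.46) was not called without any 1 of control 1 to 3 and 5 to 9 and superficial 3, 6 to 9 and 11 to 13 (0.57 to 1.12; adjusted p = 0.0542 to 0.301). A total of 296 miRNAs passed edgeR, 173 higher and 123 lower, against 252 and 66 with library totals (median log2 fold change 0.54, against 0.21). The count was 191 with depth as a covariate. Without superficial 9, miR-124-3p was at 1.90 (adjusted p = 0.127). Single libraries also moved miR-1269b (7.19 without control 9, 5.67 without superficial 3, 5.01 without superficial 7; not called by limma-voom, 1.78), miR-1269a (3.79 without superficial 3) miR-383-5p (-5.70 without superficial 12) and miR-145-5p (-2.98 without superficial 7).

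Nodular BCC against control skin had the highest miR-1269a value of the 4 subtypes. It reached 125 CPM (n = 10) and rose by 7.72 ± 1.04 (edgeR, adjusted p = 5.61e-09), with miR-135a-5p at 6.69 ± 1.10 and miR-1269b at 6.35 ± 1.85. The largest falls were in miR-383-5p (-5.55 ± 0.68) and in the striated muscle miRNAs miR-133a-3p (-4.62 ± 0.71) and miR-1-3p (-3.99 ± 0.78), and in 10 of 10 tumours each lay below every control library. The miR-183 cluster rose in 3 of 3 members, miR-96-5p by 4.81 ± 0.55 (camera adjusted p = 0.00143; adjusted p = 0.112 with an estimated correlation). In the 14q32 cluster 23 of 27 miRNAs fell and 1 rose, or 24 and 1 adjusted over the list alone (camera adjusted p = 3.07e-07; adjusted p = 0.156 with an estimated correlation). Against control skin, 339 miRNAs passed the edgeR test, 185 higher and 154 lower, and 244 higher and 115 lower with library totals (median log2 fold change 0.42, against 0.14). Without nodular 10, miR-135a-5p was at 5.24. The value of miR-1269b was 7.25 without control 9, 5.13 without nodular 3 and 2.09 with limma-voom, which did not call it. Without nodular 1, miR-383-5p was at -6.17 and miR-1-3p at -4.63.

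Micronodular BCC rose above control skin most in miR-1269a (7.08 ± 1.02; edgeR, adjusted p = 4.11e-08), miR-135a-5p (5.41 ± 1.04) and miR-424-3p (4.93 ± 0.48; adjusted p = 2.36e-13). It fell most in miR-383-5p (-5.91 ± 0.71), miR-144-3p (-4.50 ± 0.80) and miR-133a-3p (-3.79 ± 0.69). Epithelial miRNAs rose in 6 of 6 members, miR-205-5p by 2.17 ± 0.24 and miR-200b-3p by 1.77 ± 0.30 (camera adjusted p = 0.0170; adjusted p = 0.201 with an estimated correlation). Melanocyte miRNAs rose in 7 of 7, miR-509-3p by 2.74 ± 0.41 (camera adjusted p = 0.0138; adjusted p = 0.331 with an estimated correlation). The endothelial pair fell, miR-126-3p by 3.15 log2 (camera adjusted p = 7.93e-04; adjusted p = 0.0515 with an estimated correlation). In this group libraries 1 to 4 stood apart in their GC trend. Past the edgeR test were 313 miRNAs, 194 higher and 119 lower, and 326, with 172 higher and 154 lower, without the 5 libraries that stood apart; the median log2 fold change was 0.17, 0.31 with library totals and -0.08 without those 5 libraries. Without micronodular 10, miR-135a-5p was at 4.77, without micronodular 5 miR-144-3p was at -5.39, and without micronodular 4 miR-133a-3p was at -5.09.

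Infiltrative BCC differed from control skin in the largest number of miRNAs of the 4 subtypes, but it also had the most libraries (n = 22). More libraries can raise such a count, and no fit with equal group sizes was made. The highest rises were in miR-7977, from 3.25 to 361 CPM (6.78 ± 0.78; edgeR, adjusted p = 3.74e-11, above every control library in 22 of 22 tumours), miR-1269a (6.68 ± 0.98) and miR-105-5p (6.34 ± 1.62, above the control median in 14 of 22). The falls were led by miR-383-5p (-5.47 ± 0.50), miR-10a-3p (-3.74 ± 0.41) and miR-145-5p (-3.12 ± 0.29). Of 4 erythroid members 1 passed the edgeR test, miR-451a (1.80 ± 0.73), which was at 0.93 ± 0.61 without infiltrative 14 (adjusted p = 0.163), and 0 passed adjusted over the list alone. The erythroid median of 0.09 was -0.14 with the GC trend removed and -0.03 without the 5 libraries that stood apart, and camera gave the direction as down (adjusted p = 0.566). Of 9 let-7 miRNAs 7 fell, let-7c-5p by 1.65 log2, and miR-98-5p rose by 0.55 (camera adjusted p = 0.0156; adjusted p = 0.241 with an estimated correlation). Of 8 leukocyte miRNAs 5 rose, including the myeloid miR-223-3p at 2.67 ± 0.83, and 2 fell, or 3 adjusted over the list alone (camera adjusted p = 0.844). The miR-181 family rose in 4 of 4, miR-181d-5p by 4.19 ± 0.37 (camera adjusted p = 0.00204; adjusted p = 0.241 with an estimated correlation). The edgeR test called 421 miRNAs, 251 higher and 170 lower, 299 higher and 117 lower with library totals (median log2 fold change 0.71, against 0.26), and 207 higher and 210 lower with the GC trend removed. Without infiltrative 12, miR-105-5p was at 5.49, and without infiltrative 14 miR-223-3p was at 1.86. The call of miR-98-5p was lost without any 1 of infiltrative 2 to 6, 8, 10 to 12, 15 to 17, 21 and 22 (0.34 to 0.44; adjusted p = 0.0542 to 0.138).

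**Figure D3:**
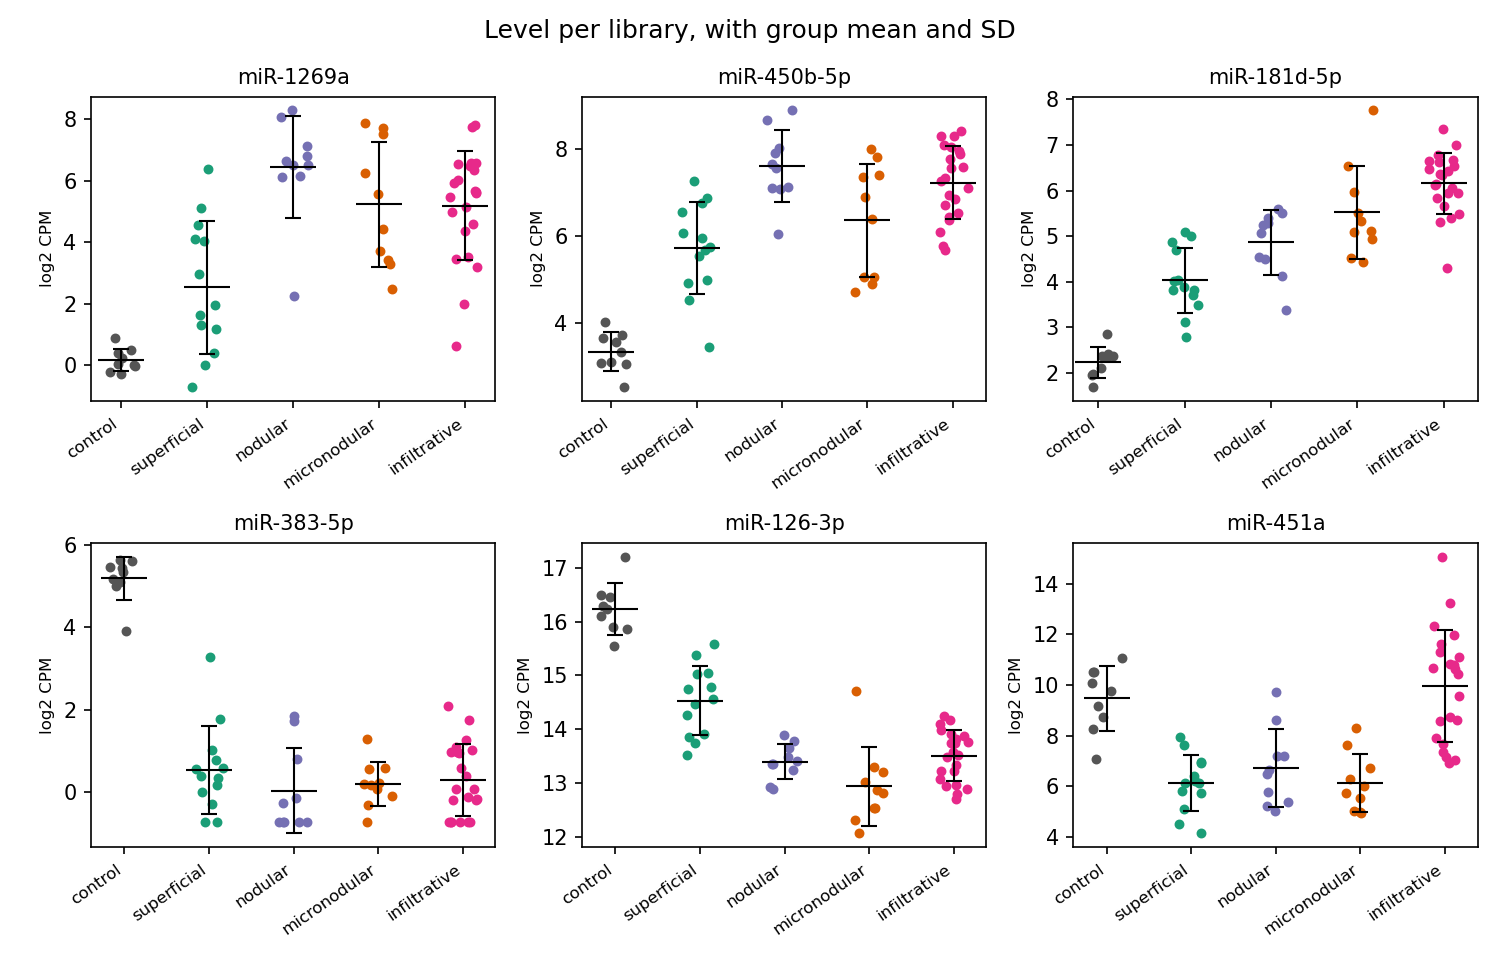
Levels of 6 miRNAs as log2 CPM, 1 point per library by group, with the group mean and SD as bars. The endothelial miR-126-3p is lower in every subtype than in control skin (log2 fold changes -1.64 to -3.15), and miR-383-5p falls by 4.67 to 5.91.

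Infiltrative and micronodular BCC, growth patterns regarded as aggressive in dermatopathology, were compared with nodular and superficial BCC. The erythroid miR-451a had the highest log2 fold change, 2.10 ± 0.50 (edgeR, adjusted p = 0.00154; above the median of the other tumours in 26 of 32), followed by miR-7977 (1.99 ± 0.40), miR-204-5p (1.67 ± 0.45) and the erythroid miR-486-5p (1.59 ± 0.46). The mean of miR-451a was 3293 CPM in infiltrative (SD 7322, n = 22), 95.4 in micronodular, 190 in nodular and 90.2 in superficial BCC, and infiltrative 14 was at 15.08 log2 CPM. The miR-181 family rose in 4 of 4 members, miR-181d-5p by 1.53 ± 0.21 and miR-181c-5p by 1.35 ± 0.20, each in 30 of 32 tumours against that median (camera adjusted p = 2.37e-05; adjusted p = 0.0597 with an estimated correlation). By subtype, the mean log2 CPM of the family was 8.15 (SD 0.58) in infiltrative and 6.32 (SD 0.47) in superficial BCC. Micronodular BCC, at 7.64 (SD 0.66), lay near nodular BCC, at 7.31 (SD 0.45). Further rises were in miR-22-5p (1.18 ± 0.14; adjusted p = 7.75e-09), miR-18a-3p (1.18 ± 0.20), miR-193a-3p (1.15 ± 0.34) and miR-652-3p (1.13 ± 0.21). In micronodular BCC alone, these last 4, miR-451a, miR-7977 and miR-486-5p passed the edgeR test against neither superficial nor nodular BCC (miR-451a 0.08 ± 0.70 and -0.99 ± 0.75; miR-7977 -0.13 ± 0.56 and 1.55 ± 0.60). Conversely, miR-204-5p passed against neither in infiltrative BCC alone (0.47 ± 0.55 and 0.82 ± 0.60). The endothelial pair fell, miR-126-5p by 0.92 log2 (camera adjusted p = 0.00390; adjusted p = 0.109 with an estimated correlation), as did the leukocyte miR-142-5p (-0.85 ± 0.25) and miR-146a-5p (-0.51 ± 0.14), 2 of 8 on that list (camera adjusted p = 0.0278; adjusted p = 0.651 with an estimated correlation). The mean log2 CPM of the endothelial pair was 12.67 (SD 0.53) in infiltrative and 12.65 (SD 0.34) in nodular BCC. It was 13.70 (SD 0.62) in superficial and 11.91 (SD 0.83) in micronodular BCC, so infiltrative BCC was not below nodular BCC. With groups weighted by their libraries miR-142-5p was at -0.34 and not called, and in infiltrative BCC alone it passed against neither superficial (-0.31 ± 0.31) nor nodular BCC (0.72 ± 0.35). Of 27 miRNAs of the 14q32 cluster 5 rose, and 3 with library totals (camera adjusted p = 0.0433; adjusted p = 0.967 with an estimated correlation). The mean log2 CPM of that cluster was 4.78 in infiltrative, 4.51 in micronodular, 3.98 in nodular and 4.75 in superficial BCC. Nodular BCC was thus the lowest, and superficial BCC lay near infiltrative BCC. No other list passed camera in this comparison. Without micronodular 3, 4 leukocyte miRNAs fell. In the 14q32 cluster 2 rose without nodular 1, 3 without superficial 3 or 6 or micronodular 6 or 9, and 8 without superficial 7.

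The other named miRNAs that fell in this comparison were miR-598-3p (-1.23 ± 0.28), miR-374a-3p (-1.06 ± 0.20), miR-196a-5p (-1.02 ± 0.37), miR-615-3p (-0.98 ± 0.35), miR-10a-3p (-0.89 ± 0.32), miR-590-3p (-0.81 ± 0.17), miR-335-5p (-0.79 ± 0.21) and miR-218-5p (-0.73 ± 0.22). Against control skin, miR-10a-3p was at -1.96 in superficial, -3.51 in nodular, -3.52 in micronodular and -3.74 in infiltrative BCC. For this miRNA, nodular BCC thus lay near micronodular and infiltrative BCC. The edgeR test called 106 miRNAs, 82 higher and 24 lower, with 22 changed at least 2-fold. The split was 69 and 38 with RLE factors, 83 and 42 with DESeq2, 67 and 56 with the GC trend removed, and 68 and 59 without the 5 libraries that stood apart, where miR-204-5p (1.05), miR-486-5p (0.76), miR-196a-5p (-0.94) and miR-218-5p (-0.53) were not called. Limma-voom did not call miR-204-5p (0.60), miR-486-5p (0.33) or miR-218-5p (-0.47). With no filter miR-196a-5p (-1.07), miR-615-3p (-1.09), miR-10a-3p (-0.94) and miR-218-5p (-0.72) were not called, nor were miR-615-3p (-0.87) and miR-10a-3p (-0.91) with libraries thinned, or miR-10a-3p (-0.86) without the 6 shallowest libraries. The call was lost for miR-204-5p without micronodular 1 (0.93; adjusted p = 0.0887), for miR-486-5p without micronodular 3 (0.91; adjusted p = 0.106) and for miR-193a-3p without micronodular 10 (0.70; adjusted p = 0.138). For miR-196a-5p it was lost without any 1 of superficial 3, 4, 6 and 8, nodular 3 and 6, and micronodular 2, 8, 9 and 10 (-1.05 to -0.96; adjusted p = 0.0503 to 0.0665). For miR-615-3p this held for superficial 7 and 8, nodular 5, 8 and 10, micronodular 2 and 6 to 10, and infiltrative 4 and 12 (-0.97 to -0.81; adjusted p = 0.05005 to 0.0875), and for miR-10a-3p for superficial 2 and 4, nodular 5, 6, 7 and 10, and micronodular 2, 7 and 10 (-0.89 to -0.83; adjusted p = 0.0520 to 0.0715).

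Nodular and superficial BCC were then compared directly. Nodular tumours were higher in miR-135a-5p (3.55 ± 0.81), miR-1269a (3.08 ± 0.70) and miR-96-5p, at 4666 CPM (n = 10) against 642 (n = 13; 2.86 ± 0.44; edgeR, adjusted p = 7.75e-06), and lower in miR-124-3p (-2.66 ± 1.01), the lymphocyte miR-150-5p (-2.13 ± 0.47) and miR-139-5p (-1.70 ± 0.32). The whole miR-183 cluster rose (camera adjusted p = 2.31e-05; adjusted p = 0.0982 with an estimated correlation). In the 14q32 cluster 19 of 27 miRNAs fell, or 24 adjusted over the list alone (camera adjusted p = 4.04e-09; adjusted p = 0.145 with an estimated correlation), and 6 of 8 leukocyte miRNAs fell (camera adjusted p = 9.14e-04; adjusted p = 0.162 with an estimated correlation). Of 6 mesenchymal miRNAs 5 fell, or 6 adjusted over the list alone (camera adjusted p = 0.00478; adjusted p = 0.218 with an estimated correlation). That count was 0 without superficial 12 or nodular 1, 1 without superficial 3, 4, 6 or 9, 2 without superficial 13, and 3 without superficial 2 or nodular 4, 7, 8 or 9, and 11 of the 14q32 cluster fell without nodular 1. In all, 155 miRNAs passed the edgeR test, 70 higher and 85 lower, and 88 with depth as a covariate, where miR-135a-5p (2.50) and miR-124-3p (-2.75) were not called. Nor was miR-124-3p with no filter (-2.64) or limma-voom (-0.66). Without superficial 9, miR-124-3p was at 1.55 (adjusted p = 0.176), its direction turned. Its call was also lost without any 1 of nodular 1 to 7 and 10 (-2.61 to -2.43; adjusted p = 0.0604 to 0.0841), and without nodular 9 it was at -3.63. Without nodular 10, miR-135a-5p was at 2.10, and without superficial 3, miR-1269a was at 3.81.

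Micronodular BCC carried less leukocyte miRNA than superficial BCC. The blood-cell miRNAs miR-142-5p and miR-142-3p fell from 3555 to 664 CPM and from 6285 to 1244 CPM (-2.42 ± 0.41 and -2.34 ± 0.40; edgeR, adjusted p = 8.60e-06 each, lower in 10 of 10 tumours than the superficial median), and miR-31-5p fell by 2.19 log2. The leukocyte list fell in 5 of 8 members, or 6 adjusted over the list alone (camera adjusted p = 2.42e-05; adjusted p = 0.0750 with an estimated correlation), and the endothelial pair fell (camera adjusted p = 2.18e-04; adjusted p = 0.0718 with an estimated correlation). Raised were miR-204-5p (2.51 ± 0.65), miR-1269a (2.45 ± 0.69) and miR-6510-3p (2.40 ± 0.41), and the miR-181 family in 4 of 4 members, miR-181c-5p by 1.90 ± 0.29 (camera adjusted p = 1.88e-04; adjusted p = 0.0750 with an estimated correlation). Epithelial miRNAs rose in 5 of 6, or 6 adjusted over the list alone, miR-200b-3p by 1.54 ± 0.26 (camera adjusted p = 0.00316; adjusted p = 0.126 with an estimated correlation). The edgeR test called 140 miRNAs, 93 higher and 47 lower, but 54 higher and 82 lower with library totals, and 85 in all with no filter on low counts. Without micronodular 1, miR-204-5p was at 1.03 (adjusted p = 0.203), it was at 1.34 and not called without the 5 libraries that stood apart, limma-voom did not call it (0.59), and without superficial 3 miR-1269a was at 3.11.

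Infiltrative BCC was compared with superficial BCC. The erythroid miR-451a averaged 3293 CPM (n = 22) against 90.2 (n = 13), a log2 fold change of 5.19 ± 0.76 (edgeR, adjusted p = 1.75e-07; above the superficial median in 22 of 22), and miR-144-5p rose by 3.36 ± 0.63. The erythroid list rose in 4 of 4 members (camera adjusted p = 0.0249; adjusted p = 0.425 with an estimated correlation). Also raised was miR-105-5p (3.44 ± 1.12), and the largest falls were in miR-150-5p (-1.89 ± 0.35), miR-10a-3p (-1.78 ± 0.39) and miR-139-3p (-1.66 ± 0.36). The miR-181 family rose in 4 of 4, miR-181c-5p by 2.18 ± 0.26 (camera adjusted p = 4.73e-05; adjusted p = 0.0774 with an estimated correlation), and let-7 miRNAs fell in 5 of 9, let-7c-5p by 0.85 log2 (camera adjusted p = 0.0486; adjusted p = 0.425 with an estimated correlation). The edgeR test called 234 miRNAs, 133 higher and 101 lower, 147 higher and 64 lower with library totals, and 108 higher and 148 lower with the GC trend removed, where the median log2 fold change turned from 0.04 to -0.15. Without infiltrative 14, miR-451a was at 4.33. The value of miR-105-5p was 6.25 without superficial 3 and 2.7 without infiltrative 12.

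Micronodular (n = 10) and nodular BCC (n = 10) differed in 78 miRNAs past the edgeR test, 51 higher and 27 lower in micronodular tumours. Higher were miR-204-5p (2.87 ± 0.71), miR-149-5p (1.6 ± 0.37) and miR-378a-5p (1.59 ± 0.30; edgeR, adjusted p = 2.31e-04), and lower were miR-9983-3p (-2.90 ± 0.90), miR-135b-5p (-2.42 ± 0.57) and miR-374a-3p (-1.75 ± 0.32; adjusted p = 2.31e-04), the last below every nodular library in 9 of 10 tumours. In the 14q32 cluster 9 of 27 rose, or 11 adjusted over the list alone (camera adjusted p = 8.33e-05; adjusted p = 0.601 with an estimated correlation), but 4 without nodular 1 and 5 without micronodular 3. The split was 43 and 38 with RLE factors, 33 and 42 with library totals, and 51 and 49 with DESeq2. The count fell to 17 with no filter on low counts, 17 with the compared groups alone, 24 with limma-voom, 45 without micronodular 3, 48 without nodular 8 and 50 without micronodular 1. It was 19 without the 5 libraries that stood apart, where miR-204-5p (1.35), miR-149-5p (1.04), miR-378a-5p (0.40), miR-9983-3p (-2.74) and miR-135b-5p (-2.08) were not called. Limma-voom did not call miR-204-5p (0.80), miR-378a-5p (0.77), miR-9983-3p (-1.49) or miR-135b-5p (-1.13), and miR-204-5p (2.73) with the compared groups alone and miR-9983-3p (-2.99) with no filter were not called. Without micronodular 1, miR-204-5p was at 1.39 (adjusted p = 0.144). Without nodular 4, miR-9983-3p was at -1.6 (adjusted p = 0.221) and miR-135b-5p at -1.33 (adjusted p = 0.0648), and without micronodular 5, miR-9983-3p was at -3.51.

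Infiltrative BCC was set against nodular BCC. It was higher in miR-451a (4.12 ± 0.81), miR-7977, at 361 against 21.1 CPM (4.10 ± 0.63; edgeR, adjusted p = 6.52e-07, above every nodular library in 22 of 22), and miR-1246 (3.86 ± 0.85), and lower in the neuronal miR-9-5p (-2.25 ± 0.55), miR-6510-3p (-2.21 ± 0.35) and miR-135a-5p (-1.89 ± 0.66). In the 14q32 cluster 17 of 27 rose and 0 fell (camera adjusted p = 1.25e-04; adjusted p = 0.609 with an estimated correlation). The miR-183 cluster fell in 3 of 3, miR-182-5p by 1.71 log2 (camera adjusted p = 0.0183; adjusted p = 0.600 with an estimated correlation), and let-7 miRNAs fell in 5 of 9, let-7c-5p by 1.43 log2 (camera adjusted p = 0.00858; adjusted p = 0.595 with an estimated correlation). Erythroid miRNAs passed the edgeR test in 4 of 4 members, but the list did not pass camera (adjusted p = 0.115). The edgeR test called 260 miRNAs, 151 higher and 109 lower, 197 higher and 80 lower with library totals, 133 and 129 with RLE factors, and 127 and 147 with the GC trend removed, where the median log2 fold change turned from 0.10 to -0.06. Without infiltrative 14, miR-1246 was at 1.01 and miR-451a at 3.25, and without nodular 3 miR-451a was at 4.82. With depth as a covariate miR-1246 (1.63) and miR-135a-5p (-0.69) were not called, nor was miR-135a-5p with limma-voom (-1.37). Without nodular 10, miR-135a-5p was at -0.43 (adjusted p = 0.616), and without infiltrative 13 at -2.61.

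Infiltrative and micronodular BCC differed in 293 miRNAs, 145 higher and 148 lower in infiltrative tumours, and 204 higher and 87 lower with library totals. The erythroid miR-451a (5.11 ± 0.85), miR-1246 (4.56 ± 0.91) and miR-9983-3p (4.53 ± 0.89) rose the most. The falls were led by miR-6510-3p, from 448 CPM (n = 10) to 46.3 (n = 22; -3.27 ± 0.35; edgeR, adjusted p = 5.80e-11, below every micronodular library in 21 of 22), miR-149-5p (-2.55 ± 0.30) and miR-204-5p (-2.04 ± 0.54). Erythroid miRNAs rose in 4 of 4 members (camera adjusted p = 0.0317; adjusted p = 0.468 with an estimated correlation). Keratinocyte differentiation miRNAs fell in 4 of 7, miR-24-3p by 0.76 log2 (camera adjusted p = 0.0317; adjusted p = 0.468 with an estimated correlation), and melanocyte miRNAs in 5 of 7, miR-513a-5p by 1.69 log2 (camera adjusted p = 0.0395; adjusted p = 0.572 with an estimated correlation). Of 9 let-7 miRNAs 6 fell, let-7b-5p by 1.44 log2, and 1 rose, or 0 without micronodular 3 (camera adjusted p = 0.0395; adjusted p = 0.468 with an estimated correlation). Leukocyte miRNAs passed the edgeR test in 5 of 8 members, each higher, with 5 higher and 1 lower adjusted over the list alone, without the list passing camera (adjusted p = 0.136). Without infiltrative 14, miR-451a was at 4.24 and miR-1246 at 1.71. Limma-voom (-0.18) and the fit without the 5 libraries that stood apart (-0.61) did not call miR-204-5p. Without micronodular 1 it was at -0.56 (adjusted p = 0.389), and without micronodular 5, miR-9983-3p was at 5.14.

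The 4 subtypes had many calls against control skin in common. All 4 called 117 miRNAs higher and 73 lower, while independent lists of the same sizes would share 7.91 and 1.94. In 50 simulations of unchanged groups, with new counts drawn for every library, 0 and 0 were shared. Those simulations drew each miRNA separately from the same mean in all groups. Calls were thus rare by design, and the 0 says little about the observed counts. With the 9 control libraries split into 5 and 4, so that the subtypes did not all share controls, the counts were 72 and 52. The fold changes of the subtypes correlated across miRNAs, which are not independent replicates, at a mean r of 0.86, against 0.57 for simulated unchanged groups and 0.83 with the controls split. The mean covariance was 2.07, against 0.0933 in the simulation and 2.09 with the controls split.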

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

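Of the tests in this part, the comparison of the falls of the stromal lists, the share of calls still tested at equal depth, and the fits with the GC trend removed, with thinned libraries and without micronodular libraries 1 to 4 were chosen only after the result was seen. Single libraries far from the rest of their group were looked for in control skin, nodular and micronodular BCC over 43 named miRNAs. The 129 tests found 16, and chance flags about 1 in 20 groups, or 6.45 here. The number given for each is the gap to the nearest library as a share of the group's range. Control library 9 was lowest for let-7b-5p (0.529), miR-383-5p (0.631), miR-196a-5p (0.542) and miR-615-3p (0.577) and highest for miR-652-3p (0.512) and miR-218-5p (0.605). Control library 2 was highest for miR-424-3p (0.553) and control library 1 lowest for miR-10a-3p (0.597). Nodular library 4 was highest for miR-105-5p (0.816; 61.9 CPM) and miR-767-5p (0.813; 150 CPM), and micronodular library 7 for the same miRNAs (0.659 and 0.679; 15.1 and 42.4 CPM). Nodular library 5 was lowest for miR-1269a (0.639; 4.14 CPM against a group median of 94.3). Micronodular library 4 was highest for miR-133a-3p (0.635), library 5 for miR-126-3p (0.530) and library 3 for miR-486-5p (0.510).

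The change from control skin differed among the 4 subtypes for 21 of 25 miRNAs named for BCC, and for 419 of all 582 (edgeR, 3-coefficient test). For miR-21-5p it was 1.23 in superficial, 1.41 in nodular, 0.42 in micronodular and 2.93 in infiltrative BCC (adjusted p = 6.22e-13), for let-7a-5p -0.37, 0.01, 0.10 and -0.97 (adjusted p = 1.65e-10), for let-7b-5p -0.38, -0.10, 0.34 and -1.09 (adjusted p = 1.14e-09), and for miR-144-3p -3.57, -2.53, -4.50 and -0.32 (adjusted p = 9.80e-08). In the same order it was -1.64, -2.87, -3.15 and -2.73 for miR-126-3p (adjusted p = 6.01e-08) and 4.36, 2.69, 4.23 and 6.78 for miR-7977 (adjusted p = 1.05e-08). The adjusted p was 2.55e-07 for both miR-424-3p and miR-145-3p, 2.06e-05 for miR-450a-5p, 1.13e-04 for miR-205-5p, 1.15e-04 for miR-450b-5p, 1.29e-04 for miR-139-3p, 2.18e-04 for miR-10a-3p, 3.56e-04 for miR-203a-3p and 7.85e-04 for miR-135a-5p. It was 0.00129 for miR-1269a, 0.00177 for miR-145-5p, 0.00547 for miR-1-3p, 0.0129 for miR-4524a-3p, 0.0157 for miR-105-5p and 0.0185 for miR-133a-3p. The remaining named miRNAs did not pass this edgeR test. Their adjusted p was 0.375 for miR-1269b, 0.292 for miR-383-5p, 0.293 for miR-767-5p and 0.0677 for miR-124-3p.

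The 27 miRNAs lower in micronodular than in nodular BCC had a median arm GC content of 39%, against 48.8% for all tested, and micronodular libraries 1 to 4 had 4 of the 5 steepest rises with GC content among the 64 libraries, 0.297 to 0.638 log2 per 10 percentage points. With each library's trend with this GC content removed, a share of 0.852 of these calls (23 of 27) stayed lower. The median log2 fold change moved from -1.34 to -1.12. A library bias that follows hairpin-arm GC content is thus argued against as the whole cause. A bias tied to the GC content of the mature sequence stays undecided, since that content was not used. Without micronodular libraries 1 to 4 the median was -1.0 (median SE 0.35, against 0.33 before), but 5 of the 27 calls remained, as the fold was smaller and fewer libraries were left. Those 4 libraries may therefore account for part of the size. Whether they account for all of it cannot be decided here. The 27 miRNAs were picked by calls that used the remaining libraries too, which favours a negative median. A biological difference between the subtypes stays open, with 12 miRNAs called in all when these libraries were left out.

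The control libraries were deeper in the median than those of each subtype, and lower depth of the tumour libraries may account for part of the 389 calls between BCC and control skin. With every library thinned to the smallest total, a share of 0.689 (268 of 389) was kept with the same sign, and 89 were no longer tested. Of the 300 still tested, all had the same sign and a share of 0.893 was called, which argues against the number of reads as the cause for these. Thinning keeps each miRNA's expected share of the reads. It therefore cannot test other differences between the libraries that go with depth. For the 89 no longer tested, depth and tissue cannot be told apart, because too few reads were left.

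Of the vascular, smooth muscle and mesenchymal miRNAs, 2 of 2, 4 of 4 and 4 of 6 were called lower in BCC than in control skin, and the lists did not pass camera with an estimated correlation (adjusted p = 0.0882, 0.0882 and 0.302). The vascular members are arms of the same hairpin, MIR126, and the smooth muscle members are arms of MIR143 and MIR145. Scaling is argued against as the cause of the 10 calls, since 10 of 10 stayed lower with RLE factors and with library totals, where 1 other mesenchymal member was called higher. Over the 55 tumours pooled, the endothelial score fell by 2.48 and the mesenchymal score by 0.79, a difference of -1.69. With the 4 subtypes weighted equally that difference was -1.64 (permutation p = 1e-05 each, the smallest that 100000 resamples can give). Equal falls of both lists are argued against. Uniform dilution by tumour cells requires equal falls only if tumour cells carry neither list. That was not measured, so dilution stays undecided. The smooth muscle score fell by 2.39 pooled and by 2.51 with equal weights, and the leukocyte score differed by 0.14 and 0.02. A hypothesis left open is that vessel and smooth muscle tissue may make up a smaller part of these specimens, which were chosen to be mostly tumour, than other stroma does, which no test here separates from expression changes within those cells.

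For each of the 12 comparisons, 100 splits of the same libraries into groups of the same sizes were fitted. In each comparison 1 of 100, the real one, gave as many calls, the smallest share that 100 splits can give. Chance is therefore argued against for these counts but not excluded. At least 1 miRNA was called in 19 of the other splits for nodular BCC against control skin, the fewest. It was 71 for infiltrative against superficial BCC, the most, while the median of the other splits was 0 or 1 calls. Calls at an adjusted p under 0.05 thus also arose in splits that ignored the groups. The adjusted p of a single miRNA may therefore be too small for these libraries. The margin was narrow for micronodular against nodular BCC, at 78 calls against 70 in another split. The splits also treated the libraries as independent, which the labels do not state. The splits were not drawn under the alternatives, which for micronodular against nodular BCC gave as few as 17 calls. The real count and the highest of the other splits were 389 and 39 for BCC against control skin, and 296 and 115, 339 and 124, 313 and 210, and 421 and 32 for superficial, nodular, micronodular and infiltrative BCC against control skin. They were 106 and 34 for infiltrative and micronodular against nodular and superficial BCC. Between subtypes they were 155 and 42 for nodular against superficial, 140 and 105 for micronodular against superficial, 234 and 20 for infiltrative against superficial, 78 and 70 for micronodular against nodular, 260 and 117 for infiltrative against nodular, and 293 and 126 for infiltrative against micronodular BCC.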

How the results depend on the processing

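The tests with thinned libraries, with the GC trend removed and without the 5 libraries that stood apart were chosen only after the result was seen. Over the named miRNAs, 1180 of 1232 values kept their direction and side of the threshold, 46 were weaker, 5 were stronger and 1 reversed, which was let-7a-5p in BCC against control skin, at 0.014 with depth as a covariate, where the cause was not tested. Of the weaker ones 14 came with limma-voom and 11 without the 5 libraries that stood apart. Named miRNAs that an alternative no longer tested were left out of the 1232 values and not counted as lost. The count of calls moved by over 1.5 times with depth as a covariate for superficial BCC against control skin (191) and nodular against superficial BCC (88), and with no filter for micronodular against superficial BCC (85). For micronodular against nodular BCC it was 17 with no filter, 24 with limma-voom, 17 with the compared groups alone and 19 without the 5 libraries that stood apart, of which 12 were also among the 78. Fewer libraries remained in the last of these; the cause of the others was not tested. Apart from single libraries left out, the other alternatives left each count within 1.5 times. Besides the splits given with each comparison, the larger of the higher and lower counts changed sides, for causes not tested, in these fits (higher and lower): superficial BCC against control skin with the stricter filter (119 and 120), nodular against control skin (155 and 159) and infiltrative against nodular BCC (118 and 124) with the compared groups alone, and infiltrative against superficial BCC with the stricter filter (94 and 95). It did so for nodular against superficial BCC with no filter (60 and 44), without the 6 shallowest libraries (66 and 60) and without the 5 that stood apart (86 and 81). For micronodular against nodular BCC it did so with no filter (7 and 10), the compared groups alone (5 and 12) and without those 5 libraries (7 and 12). For infiltrative against micronodular BCC it did so with no filter (200 and 156), depth as a covariate (136 and 135), DESeq2 (210 and 178), limma-voom (157 and 129) and without those 5 libraries (151 and 126). Leaving out 1 library at a time gave 372 to 396 calls for BCC against control skin, 270 to 306 for superficial, 331 to 347 for nodular, 303 to 320 for micronodular and 408 to 419 for infiltrative BCC against control skin, and 84 to 128 for infiltrative and micronodular against nodular and superficial BCC. Between subtypes the ranges were 126 to 171 for nodular and 113 to 163 for micronodular against superficial, 208 to 245 for infiltrative against superficial, 45 (without micronodular 3) to 115 (without micronodular 5) for micronodular against nodular, with 48 without nodular 8 and 50 without micronodular 1, 239 to 275 for infiltrative against nodular and 270 to 302 for infiltrative against micronodular BCC. With Spearman distance, group accounted for 54.8% and subtype for 37.7% of the variance. No paired analysis was possible because the labels give no replicate numbers shared between groups, and the numbers used here are names only. Depth limited the rarest miRNAs: at 927831 reads per library, 89 of the 389 miRNAs called in BCC were no longer tested.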

Other observations

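The tests in this part, of miRNA genes lying within 10000 bases of each other, were described as clusters only after the result was seen, and the features below were picked after their values were seen. Mature miRNAs with several annotated genes were left out of the clusters. All 9 tested mature miRNAs with a single gene in the MIR450B to MIR424 cluster on chromosome X (134540185 to 134546711, GRCh38) rose in BCC against control skin, with a median log2 fold change of 2.95. Left out of these 9 was miR-450a-5p, which rose by 4.34 ± 0.45. The most abundant, miR-424-5p, went from 216 CPM in control skin (n = 9) to 2455 CPM in BCC (n = 55; 3.46 ± 0.50, SE; edgeR, adjusted p = 2.16e-08), and miR-503-5p rose by 2.75 ± 0.41 and miR-542-3p by 2.95 ± 0.42. Of the 9, 6 were lower in infiltrative than in nodular BCC (median -0.95). The 4 mature miRNAs of MIR30B and MIR30D on chromosome 8 (134800520 to 134804945) fell in BCC, miR-30b-5p by 0.71 on the log2 scale. The 4 of the MIR506 to MIR508 cluster on chromosome X (147230720 to 147237027) rose, miR-506-3p by 2.38 ± 0.47.

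The miR-132 and miR-212 genes, neighbours on chromosome 17 (2049908 to 2050380), had their highest mean levels in infiltrative BCC. There miR-132-3p stood at 290 CPM (n = 22), against 111 in nodular BCC (n = 10; 1.39 ± 0.19; edgeR, adjusted p = 2.18e-08) and 67.4 in control skin, and 4 of the 4 mature miRNAs of the pair rose against nodular BCC (median 1.58). At 14q32 the annotation gave separate clusters. Again, mature miRNAs with several annotated genes were left out. Of 37 tested mature miRNAs with a single gene from MIR379 to MIR656 (chromosome 14, 101022066 to 101066801) 25 fell and 1 rose in BCC against control skin. Of 11 such miRNAs from MIR493 to MIR136 (100869060 to 100884783) 5 fell and 1 rose. Against nodular BCC, infiltrative BCC was higher in 22 of the 37 and in 6 of the 11, and lower in 0 of either.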
